A study of Mus musculus with 16 samples.

How the data were processed

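Kidneys were from wild-type C57BL/6J male mice. Pieces of cortex were frozen when the animals were killed, total RNA was isolated with a spin-column kit, and polyadenylated RNA was made into strand-marked libraries with the TruSeq Stranded mRNA kit, per the labels' protocols. Groups were taken from the sample titles and treatment labels: sedentary, and forced treadmill running of 40 minutes at 70% capacity over 1 day (24 h), 1 week or 2 weeks, with 4 libraries each. The labels number the libraries of a group but do not say in so many words that each came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical. The titles carry a letter that no label explains and that is one for sedentary and another for all exercised libraries, so that whatever it marks cannot be told apart from exercise. Whether the 24 h group ran within 1 day or was killed 24 h after a single run is left open by the labels. The time from the last run to death is not given in the sources used here.

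The deposited table holds raw counts per gene, whole numbers that were not normalized. The reads were checked with FastQC 0.10.1 and counted with HTSeq 0.10.0 on the mouse build GRCm38 (mm10), per the submitters' processing notes. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. How the authors counted reads that match near-identical copies is likewise not given, so pseudogenes, paralogs and antisense genes are reported as uncertain. The table has 55414 genes identified by Ensembl ID and 24 columns of counts. Its 8 columns that match no sample were not used in any step, and the other 16 were joined to samples by name. Gene symbols were taken by ID from GENCODE M21, in which 52081 IDs (94.0%) have a name, holding 99.4% of the counts. The other IDs were kept under their ID and not named, and the most abundant of them took 0.585% of the counts on average. Gene positions are those of GENCODE M21 on GRCm38, 1-based.

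Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which left 16126, library sizes were scaled by TMM, and the robust quasi-likelihood F-test was used with Benjamini-Hochberg adjustment and a threshold of 0.05. All 16 libraries entered 1 fit, so that the 4 groups share an estimate of the spread. Each duration was compared with sedentary mice and with each other duration, and all 4 groups were compared together. Values after ± are SD over libraries for CPM (TMM-scaled with the cpm function of edgeR) and shares, and SE for log2 fold changes. DESeq2 1.42.0 and voom with sample quality weights in limma 3.58.1 were run as alternatives.

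There were 49 gene lists of cell types, transport, metabolism and stress, of which 45 had at least 5 tested members. They were compared with the other genes by camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, and adjusted over the 45 lists. Camera with a correlation estimated for each list, and fry, a rotation test of whether a list's genes move one way, were run beside it. Some lists share members. Lists under 5 tested members are given as summed CPM. For each list the number of members that pass is also given with p adjusted over the list alone.

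The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule, a gene was named in a comparison with sedentary mice if it was among the 8 with the largest rise or the 8 with the largest fall past the threshold, with a mean log2 CPM of at least 0, no overlap between the groups and a symbol that is not a clone name, or among the 4 of smallest p of a list past the threshold. Where no gene passed, as in all 3 such comparisons, the 10 of smallest p were named instead. Between durations the 4 largest rises and falls were named by the same criteria. Ren1, Slc12a3, Slc9a3, Havcr1, Lcn2, Adgre1, Cd3e, Per1, Nr1d1, Arntl, Xist and Ddx3y were named always. List members given as examples beyond this rule were picked by their small p after the values were seen.

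Totals ranged from 39766260 to 66852397 counts. Single values per library were compared by a two-sided exact permutation test over 70 arrangements. To see whether 1 library had been deposited 2 times, counts of genes with 20 or more counts were compared between libraries of the same group by a chi-square statistic, which exceeded its degrees of freedom in each such pair; pairs across groups were not compared. The scripts were tested on simulated counts drawn from the real means and library sizes, once per comparison. In each, 200 genes were changed, and 10 lists of 12 further genes were shifted by 0.3 in log2. Genes were drawn independently of each other, and no library was made to stand apart. False calls were those of genes neither changed nor shifted, while the totals of genes and of calls include all genes. EdgeR recovered 49.3% of the genes changed 1.5-fold, 74.6% of those changed 2-fold and 95.5% of those changed 3-fold in the simulation of 24 h against sedentary mice, with 6 false calls among 15956 genes. For 1 wk the shares were 41.8%, 76.1% and 87.9% with 6 false calls among 15968 genes, and for 2 wk 56.7%, 76.1% and 93.9% with 10 among 15963. DESeq2 made 14, 22 and 24 false calls in these simulations among 178, 183 and 202 calls, a share over its threshold of 0.05. EdgeR's 6, 6 and 10 were among 163, 150 and 171 calls. Voom with quality weights made 5, 6 and 10 among 160, 149 and 173. For these 2 tools the share was over 0.05 at 2 wk only. To judge correlations between comparisons that share the sedentary libraries, unchanged groups, the sedentary one included, were simulated 20 times. The real sedentary libraries were also split between the comparisons.

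Alternatives were RLE and upper-quartile scaling, no filter on low counts or a filter of at least 1 CPM in 4 libraries, only the 8 libraries of the groups compared, a 1.2-fold or an adjusted p of 0.01 threshold, the replicate number as a factor, and leaving out each library in turn. Chosen after the data were seen were a fit without mitochondrially encoded genes and the most abundant unnamed ID, an exact test of list means, a fit without 2 libraries that stood apart, and DESeq2's likelihood ratio test.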

Results

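The transcriptome of the kidney cortex was measured by RNA sequencing in male C57BL/6J mice, a common inbred laboratory strain, that were kept sedentary or made to run on a treadmill. The study set the blood pressure-driven excretion of salt and water by the kidney, and its immune cells, against exercise training. Runs lasted 40 minutes at 70% of the animal's capacity and were given over 1 day (the 24 h group), 1 week (1 wk) or 2 weeks (2 wk). The labels do not say whether the 24 h group ran within 1 day or was killed 24 h after a single run, so its values stand for either. Each of the 4 groups had 4 libraries. Total counts ranged from 39766260 to 66852397 per library, and between 20950 and 21897 genes had at least 1 count in a library. The counts came to 49175000 ± 5221100 per library in sedentary mice (SD, n = 4), 45831000 ± 4570400 at 24 h, 46187000 ± 3885100 at 1 wk and 50712000 ± 10829000 at 2 wk. The precision for a typical gene was set by the spread between libraries, with a median standard error of a log2 fold change of 0.144 over the 16126 genes tested. Libraries of the same group differed by more than sampling noise in each pair.

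Sex-linked transcripts matched male animals in all 16 libraries. Xist, the RNA that silences the inactive X chromosome, had at most 1 count in a library, whereas the Y-linked gene Ddx3y had 485 to 1197 counts. Across all 4 groups together, edgeR's quasi-likelihood test found differences in 2 genes, Asns (adjusted p = 0.0218) and Atf5 (adjusted p = 0.0358). At an unadjusted p under 0.05 the number was 1407 of 16126 genes. The first 3 principal components of log2 CPM held 17.6%, 12.8% and 10.99% of the variance. The numbers in the library names ran in group order, and an unexplained letter in the titles separates sedentary from exercised libraries, so that the order of preparation and whatever the letter marks cannot be told apart from the group.

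The comparison at 24 h asked how the cortex of that group differed from the sedentary state. Transcripts encoded by the mitochondrial genome took 2.47 ± 0.23% of all counts at 24 h (SD, n = 4) and 3.91 ± 0.41% in sedentary mice. The libraries of the groups did not overlap, with 2.16 to 2.71% at 24 h and 3.61 to 4.52% in sedentary mice. A two-sided exact permutation test gave p = 0.0286, the smallest that 4 libraries against 4 allow, and an adjusted p of 0.0857 over the 3 comparisons with sedentary mice. All 7 mitochondrially encoded genes tested were lower, with a median log2 fold change of −0.77. The gene of cytochrome b, mt-Cytb (GRCm38, chromosome M, 14145 to 15288), was at 6661 ± 502 CPM against 11826 ± 1452 CPM, a log2 fold change of −0.83 ± 0.15 (SE). The respiratory chain subunits mt-Nd2 (−0.77 ± 0.15) and mt-Co1 (−0.66 ± 0.13) were also among the 10 genes of smallest p, and for these 3 genes edgeR's adjusted p was 0.0972. All 7 genes passed when p was adjusted over the list alone, and none when adjusted over all genes. The list lay below the other genes by camera with a preset correlation (adjusted p = 1.81e-11), but not with an estimated one (adjusted p = 0.198 with an estimated correlation). By fry, which asks only whether a list's own genes move one way, its adjusted p was 0.0132, the 1 list of 45 that passed at 24 h. Nuclear genes of mitochondrial biogenesis and the respiratory chain had a median log2 fold change of −0.01 over 20 genes (adjusted p = 0.558).

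The lists of protein folding and of stress in the endoplasmic reticulum were higher at 24 h by camera with the preset correlation, but not with an estimated one (adjusted p = 0.393 for each) or by fry (0.227 for each). The genes with the smallest p were Asns, which makes asparagine (ENSMUSG00000029752, GRCm38 chromosome 6, 7675169 to 7693254, minus strand), and Atf5, a transcription factor of the integrated stress response (ENSMUSG00000038539, chromosome 7, 44812256 to 44816658, minus strand). Asns was at 10.5 ± 0.93 CPM against 5.06 ± 0.91 in sedentary mice, 2.07-fold, and Atf5 at 28.9 ± 1.4 CPM against 19.7 ± 1.6, 1.47-fold. For both genes all 4 libraries at 24 h lay above all sedentary libraries, and edgeR's adjusted p was 0.0621. All 13 heat shock and folding genes had positive log2 fold changes, with a median of 0.58, and 11 passed when adjusted over the list alone. Among them were the chaperones Hsph1 (0.87 ± 0.23, at 198 ± 79.4 CPM against 108 ± 10.4 CPM), Hspa1b (1.59 ± 0.46) and Hspa1a (1.38 ± 0.41). In the endoplasmic reticulum stress list, which holds Asns, 12 of 14 genes were positive, the median was 0.42 and 9 passed when adjusted over the list alone. Its members included Creld2 (1.202 ± 0.272), Manf (0.97 ± 0.25) and the chaperone BiP, Hspa5 (0.64 ± 0.20). Camera's adjusted p was 2.35e-08 for the heat shock list and 2.3e-07 for the endoplasmic reticulum list. The 3rd library at 24 h stood far above the others in both lists, at a mean log2 CPM 1.33 and 1.03 above the sedentary mean. In the heat shock list the 4th was also high, at 0.75. The 1st and 2nd were at 0.12 and 0.22 there, and the highest sedentary library at 0.07. Without the 3rd 24 h library the list medians were 0.29 and 0.22, and camera's adjusted p was 2.34e-05 and 0.000267.

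**Figure D1:**
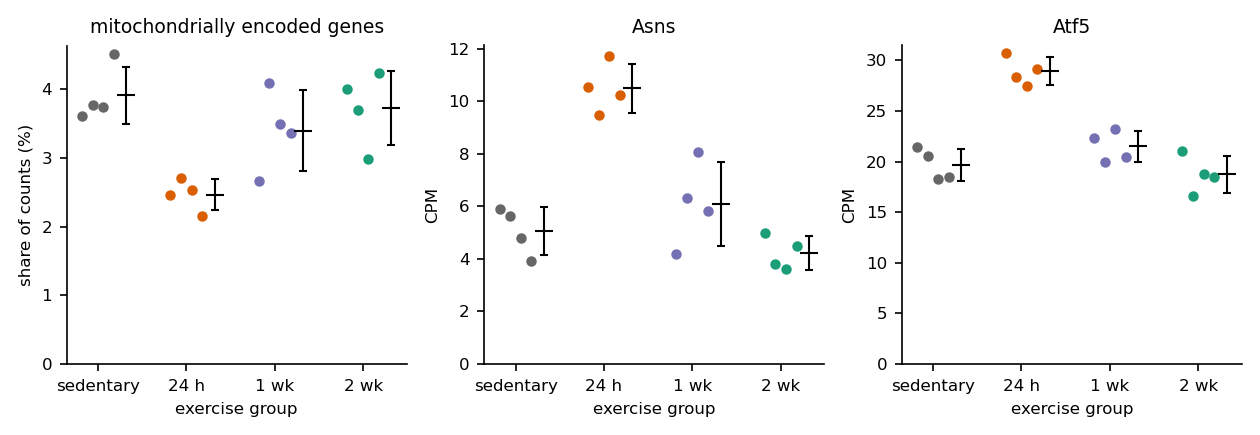
Share of counts on mitochondrially encoded genes (%), and CPM of Asns and Atf5, in each of 16 libraries by exercise group; points are libraries, and the bars beside them the mean and SD (n = 4). The 24 h libraries lie at 2.16 to 2.71% of counts, below the sedentary range of 3.61 to 4.52%, and above all sedentary libraries for Asns and Atf5.

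The lists of kidney injury and of fibroblasts and matrix were also higher at 24 h by camera, but not with an estimated correlation (adjusted p = 0.393 for each) or by fry (0.294 for each). In the injury list 13 of 14 genes were positive, with a median log2 fold change of 0.39. The chaperone clusterin, Clu (0.61 ± 0.20, 408 ± 44.0 CPM against 266 ± 57.4 CPM), osteopontin, Spp1 (0.42 ± 0.14), and the fibrinogen chain Fgb (1.31 ± 0.45) were the 3 that passed when adjusted over the list alone. The tubular injury marker Havcr1 was at 10.6 ± 10.3 CPM against 3.44 ± 1.61 CPM (edgeR adjusted p = 0.488) and Lcn2 at 4.04 ± 2.05 CPM against 1.99 ± 0.42 CPM (adjusted p = 0.48). The fibroblast list had a median of 0.23 with 2 of 12 genes passing when adjusted over the list alone, the collagen genes Col1a1 (0.58 ± 0.17) and Col1a2 (0.48 ± 0.15). The adjusted p by camera was 0.000648 for each of these lists. Without the 3rd 24 h library the medians were 0.26 and 0.15. The 2nd 24 h library did not share either rise. Its list means were −0.09 for injury and −0.07 for fibroblasts relative to the sedentary mean.

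Targets of PPAR-alpha and fatty acid oxidation had a median of 0.13, with Angptl4 (0.83 ± 0.20) and Ucp2 (0.65 ± 0.21) among the genes passing when adjusted over the list alone. Cholesterol synthesis (median 0.20), the glucocorticoid response (0.20) and ribosomal proteins (0.07) were higher, and solute and drug carriers of the proximal tubule (−0.15) lower. With an estimated correlation none of these 5 lists was called (adjusted p = 0.931 for ribosomal proteins and 0.393 for each of the other 4). With the preset correlation camera's adjusted p was 0.0023, 0.0162, 0.0481, 0.0248 and 0.0147 in the order given. None of the carriers, ribosomal or glucocorticoid genes passed when adjusted over the list alone. All 5 calls were lost without the 3rd 24 h library, with adjusted p of 0.0841 for fatty acid oxidation, 0.0729 for cholesterol synthesis, 0.274 for the glucocorticoid response, 0.732 for ribosomal proteins and 0.0735 for the carriers. The medians were then 0.044, 0.117, 0.12, 0.022 and −0.137 in that order. Without the 1st 24 h library, cholesterol synthesis (0.0508), the glucocorticoid response (0.062) and the carriers (0.0595) were lost, and the ribosomal median was 0.12 (adjusted p = 0.000351). Without the 4th, the glucocorticoid response (0.0607) and ribosomal proteins (0.152) were lost. Without the 2nd, the glucocorticoid median was 0.42. Among the sedentary libraries, leaving out the 1st (0.156) or the 3rd (0.11) ended the call of the glucocorticoid list, and leaving out the 4th that of ribosomal proteins (0.12), with a carrier median of −0.08.

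Immune cell lists were not called at 24 h. Median log2 fold changes were 0.16 for macrophages (adjusted p = 0.195), 0.11 for T cells (0.834), −0.52 for B cells (0.167), −0.07 for natural killer cells (0.558), 0.13 for MHC class II presentation (0.531) and 0.25 for chemokines, cytokines and adhesion, where 11 of 11 genes were positive (0.0596). In the plasma cell list (median 0.51, adjusted p = 0.169) the immunoglobulin genes Igha (1.16 ± 0.32) and Jchain (1.85 ± 0.56) passed when adjusted over the list alone. The 1st 24 h library had the mean of that list 0.99 and that of T cell genes 0.83 above the sedentary mean.

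EdgeR called 0 of 16126 genes at 24 h at an adjusted p under 0.05, where 1439 had an unadjusted p under 0.05 (724 higher and 715 lower) and 806 were the number chance gives. DESeq2, whose share of false calls in simulated data was over the threshold, called 78 genes (46 higher, 32 lower) and limma's voom with quality weights 59 (31 higher, 28 lower). In the simulation of 24 h against sedentary mice, voom made 5 false calls among 160 and edgeR 6 among 163, both shares under the threshold. Simulated genes varied independently, and no simulated library stood apart as the 3rd 24 h library did. These shares therefore need not hold for the real counts. The remaining genes of the 10 with the smallest p had an adjusted p of 0.0972. They were Lpo (1.41 ± 0.26), Chka, which starts phosphatidylcholine synthesis (0.45 ± 0.09), Zfp977 (−2.92 ± 0.56, at 0.044 CPM against 0.35 CPM) and 2 transcripts that cannot be separated with certainty from near-identical copies. These 2 were Gm11273 (0.98 ± 0.19) and the pseudogene Rpl28-ps1 (0.90 ± 0.17), which resembles a ribosomal protein gene. The renin gene Ren1 was at 109 ± 39.4 CPM against 74.7 ± 18.3 CPM (adjusted p = 0.624), and the sodium transporters Slc12a3 (0.18 ± 0.14, adjusted p = 0.733) and Slc9a3 (−0.16 ± 0.15, adjusted p = 0.796) did not differ by the test. Adgre1 (0.42 ± 0.26), Cd3e (−0.003 ± 0.32), Per1 (0.16 ± 0.27), Nr1d1 (0.09 ± 0.18), Arntl (0.23 ± 0.27) and Ddx3y (−0.02 ± 0.19) had adjusted p of 0.658 to 0.999. The sign for Cd3e changed with the size factors of DESeq2.

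After 1 week of running, the lists of endothelium and of some immune cells were lower than in sedentary mice by camera, but not with an estimated correlation. All 10 endothelial genes had negative log2 fold changes with a median of −0.37, and 9 passed when adjusted over the list alone. Among them were the receptor of vascular endothelial growth factor Kdr (−0.53 ± 0.15, 26.1 ± 2.73 CPM against 37.6 ± 3.62 CPM), Emcn (−0.45 ± 0.14) and the glomerular endothelial gene Ehd3 (−0.35 ± 0.12). All 13 macrophage genes (median −0.36), all 10 genes of MHC class II presentation (median −0.24) and 19 of 20 interferon response genes (median −0.23) were also negative. Examples were Mrc1 (−0.68 ± 0.26), H2-Ab1 (−0.39 ± 0.14) and Ifit1 (−0.70 ± 0.22), and none of the genes of these 3 lists passed when adjusted over the list alone. The adjusted p by camera was 5.06e-08 for endothelium, 1.81e-05 for macrophages, 0.00032 for MHC class II and 5.4e-06 for the interferon response, and 0.435 for each with an estimated correlation. The 3rd 1 wk library did not share the fall of 3 of these lists. Relative to the sedentary mean its list means were 0.02 for macrophages, 0.04 for MHC class II and 0.14 for the interferon response, against −0.37 to −0.58 in the other 1 wk libraries. Without it the medians of the interferon and MHC class II lists were −0.44 and −0.38. In the dendritic cell list (median −0.50, but −0.054 with adjusted p = 0.174 when only genes of at least 1 CPM in 4 libraries were kept) the lectin receptor Cd209a passed when adjusted over the list alone (−1.09 ± 0.26, 0.80 ± 0.23 CPM against 1.70 ± 0.34 CPM). With an estimated correlation the adjusted p of this list was 0.435. The T cell list (median −0.28, adjusted p = 0.461 with an estimated correlation) was lower as well, with 1 of 9 genes passing when adjusted over the list alone. That gene was Cd3e, a chain of the T cell receptor complex, with a log2 fold change of −1.28 ± 0.35 at 0.19 ± 0.06 CPM against 0.47 ± 0.04 CPM. The lists of monocytes (median −0.37, adjusted p = 0.0656), natural killer cells (−0.43, 0.0854), B cells (−0.34, 0.153) and plasma cells (−0.04, 0.196) were not called.

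The list of the distal convoluted and connecting tubule was higher at 1 wk by camera, with 10 of 10 positive log2 fold changes and a median of 0.30. It was not called with an estimated correlation (adjusted p = 0.435), by fry (0.392) or without the 4th 1 wk library (0.0578). The thiazide-sensitive sodium chloride cotransporter Slc12a3, a member of that list, was at 498 ± 76.6 CPM against 404 ± 68.2 CPM (0.30 ± 0.14, edgeR adjusted p = 0.796). Cholesterol synthesis was higher (median 0.19, adjusted p = 0.435 with an estimated correlation), with 4 of 14 genes passing when adjusted over the list alone, among them Fdps (0.50 ± 0.18), Lss (0.30 ± 0.10) and Sqle (0.27 ± 0.10). Ribosomal proteins (0.12, positive in 80 of 81), erythroid cells (0.61), intercalated cells (0.13), sodium transport (0.10) and fatty acid oxidation (0.09) were higher, and smooth muscle and mesangium (−0.23) and fibroblasts (−0.19) lower, with no gene of these 7 lists passing when adjusted over the list alone. With an estimated correlation none of the 7 was called (adjusted p = 0.629 for ribosomal proteins, 0.435 for smooth muscle and 0.461 for the other 5). Camera's adjusted p was 0.00262 for the distal tubule, 0.000277 for cholesterol synthesis, 1.9e-05 for ribosomal proteins and 0.0128 to 0.0455 for dendritic cells, T cells and the other 6 lists. By fry no list passed at 1 wk.

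Most of the weaker calls at 1 wk were lost in more than 1 of the 8 fits that left out a library. T cells, intercalated cells and erythroid cells were each lost in 5 of these fits, and ribosomal proteins and the distal tubule in 1. Without the 1st 1 wk library, camera's adjusted p was 0.0505 for dendritic cells, smooth muscle and fibroblasts, 0.149 for T cells, 0.211 for sodium transport and 0.139 for intercalated cells. Without the 2nd, it was 0.0664 for dendritic cells, T cells and fatty acid oxidation, 0.0542 for erythroid cells and 0.146 for intercalated cells. Without the 3rd, it was 0.63 for ribosomal proteins (median 0.02) and 0.294 for erythroid cells (median 0.20), and the smooth muscle median was −0.35. Without the 4th, it was 0.117 for smooth muscle, 0.199 for fibroblasts, 0.123 for T cells, 0.426 for sodium transport, 0.123 for intercalated cells and 0.084 for erythroid cells, and the medians of ribosomal proteins and cholesterol synthesis were 0.25 and 0.30. Among the sedentary libraries, leaving out the 1st ended the calls of smooth muscle (0.0989), T cells (0.0646), fatty acid oxidation (0.0654) and erythroid cells (0.0799), with an intercalated median of 0.21. Leaving out the 3rd ended those of T cells (0.0749), sodium transport (0.103) and intercalated cells (0.0628). Leaving out the 4th ended those of sodium transport (0.154), intercalated cells (0.278) and erythroid cells (0.099), with a fibroblast median of −0.11 (adjusted p = 0.0455). The sodium transport median changed sign, to −0.005, in voom with quality weights.

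EdgeR called 0 genes at 1 wk, where 975 had an unadjusted p under 0.05 (375 higher and 600 lower). DESeq2 called 12 genes (6 higher, 6 lower) and voom with quality weights 6 (3 higher, 3 lower). The smallest p was that of Gadd45g, a stress-inducible growth arrest gene (ENSMUSG00000021453, chromosome 13, 51846678 to 51848468), at 50.2 ± 10.8 CPM against 23.8 ± 1.499 CPM (1.08 ± 0.19, adjusted p = 0.263). Without the 1st 1 wk library edgeR called 1 gene, Gadd45g. The basement membrane gene Nid1 (−0.70 ± 0.15), Prok1 (−1.001 ± 0.211), the transcription factor Ets1 (−0.48 ± 0.11) and the leukocyte surface gene Spn (−0.82 ± 0.19) followed, with Ltk (1.77 ± 0.38, at 0.37 CPM against 0.11 CPM). The pseudogene Gm6807 (1.05 ± 0.22), a further clone-named pseudogene, Rpl28-ps1 (0.89 ± 0.17) and Gm11273 (0.89 ± 0.19) were also among the 10 and are uncertain for the reason given above. Adjusted p for these 9 genes was 0.369 to 0.378. Ren1 (0.02 ± 0.30), Slc9a3 (0.12 ± 0.15), Havcr1 (0.48 ± 0.66), Lcn2 (0.42 ± 0.41), Adgre1 (−0.33 ± 0.26), Per1 (−0.04 ± 0.27), Nr1d1 (−0.02 ± 0.18), Arntl (−0.12 ± 0.27) and Ddx3y (−0.10 ± 0.19) had adjusted p of 0.932 to 0.999.

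**Figure D2:**
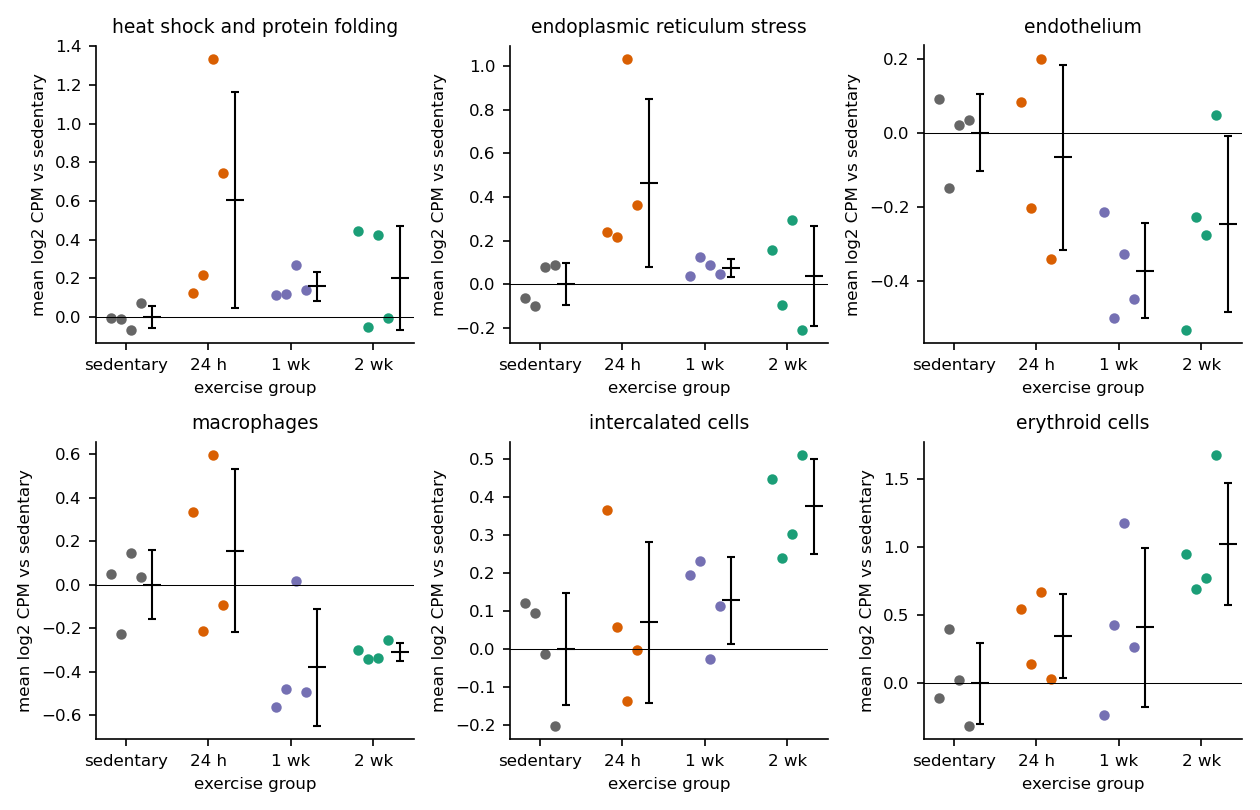
Mean log2 CPM over the genes of 6 lists in each of 16 libraries, relative to the mean of the sedentary libraries; points are libraries, and the bars beside them the group mean and SD (n = 4). The 3rd 24 h library lies at 1.33 in the heat shock list and 1.03 in the endoplasmic reticulum list.

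After 2 weeks of running, 3 lists of the distal nephron were higher by camera, but not with an estimated correlation (adjusted p = 0.158 for intercalated cells and for the distal convoluted and connecting tubule, 0.279 for principal cells). In these segments the last part of the filtered sodium is reabsorbed and acid is secreted. The smallest p was that of Foxi1, the transcription factor that specifies intercalated cells (ENSMUSG00000047861, GRCm38 chromosome 11, 34204338 to 34208089, minus strand), at 33.8 ± 6.73 CPM against 19.2 ± 1.46 CPM, 1.76-fold (0.82 ± 0.14, edgeR adjusted p = 0.0591). In the intercalated cell list 9 of 10 genes were positive, the median was 0.40 and 6 passed when adjusted over the list alone, among them the proton pump Atp4a (0.43 ± 0.11), Insrr (0.55 ± 0.18) and the anion exchanger pendrin, Slc26a4 (0.39 ± 0.14). In the distal convoluted and connecting tubule, 9 of 10 genes were positive with a median of 0.42, and 6 passed when adjusted over the list alone. They included the sodium-calcium exchanger Slc8a1 (102 ± 20.5 CPM against 56.03 ± 12.01 CPM, 0.87 ± 0.18, edgeR adjusted p = 0.229), Slc12a3 (566 ± 57.5 CPM against 404 ± 68.2 CPM, 0.49 ± 0.14, adjusted p = 0.36) and the calcium channel Trpv5 (0.76 ± 0.19). The principal cell list had a median of 0.37, and 5 of 10 genes passed when adjusted over the list alone, among them Hsd11b2, which inactivates corticosterone in these cells (0.59 ± 0.15). The water channel Aqp2 was at 206 ± 75.0 CPM against 182 ± 21.6 CPM (0.18 ± 0.21).

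All 3 subunits of the epithelial sodium channel were in the sodium transport list, which was higher at 2 wk by camera (median 0.24, positive in 17 of 20) but not with an estimated correlation (adjusted p = 0.158) or by fry (0.0597). Their log2 fold changes were 0.53 ± 0.12 for Scnn1a (144 ± 22.1 CPM against 99.8 ± 14.8 CPM), 0.55 ± 0.14 for Scnn1b and 0.57 ± 0.12 for Scnn1g (46.1 ± 7.69 CPM against 31.0 ± 2.98 CPM, edgeR adjusted p = 0.185). They were among 8 genes that passed when adjusted over the list alone, as were the regulators Nedd4l (0.36 ± 0.10), Wnk1 (0.39 ± 0.14) and Wnk4 (0.34 ± 0.13). The list shares Scnn1b, Scnn1g, Slc12a3, Wnk1 and Slc26a4 with the 3 segment lists, so these are not independent of each other. The proximal exchanger Slc9a3 was at 85.9 ± 8.82 CPM against 85.9 ± 4.85 CPM (adjusted p = 0.999), and its sign changed with upper-quartile scaling. The adjusted p by camera was 1.1e-06 for intercalated cells, 1.25e-05 for the distal convoluted and connecting tubule, 0.000459 for principal cells and 8.4e-06 for sodium transport. By fry the adjusted p was 0.04995 for intercalated cells, just under the threshold, 0.0731 for the distal convoluted and connecting tubule and 0.169 for principal cells. Without the 4th 2 wk library the principal cell median was 0.19. Genes of the renal medulla were lower at 2 wk (median −0.29, camera's adjusted p = 0.00645, adjusted p = 0.363 with an estimated correlation), with none of 10 passing when adjusted over the list alone. That call was lost without the 2nd 2 wk library (adjusted p = 0.117), and without the 1st the median was −0.17.

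**Figure D3:**
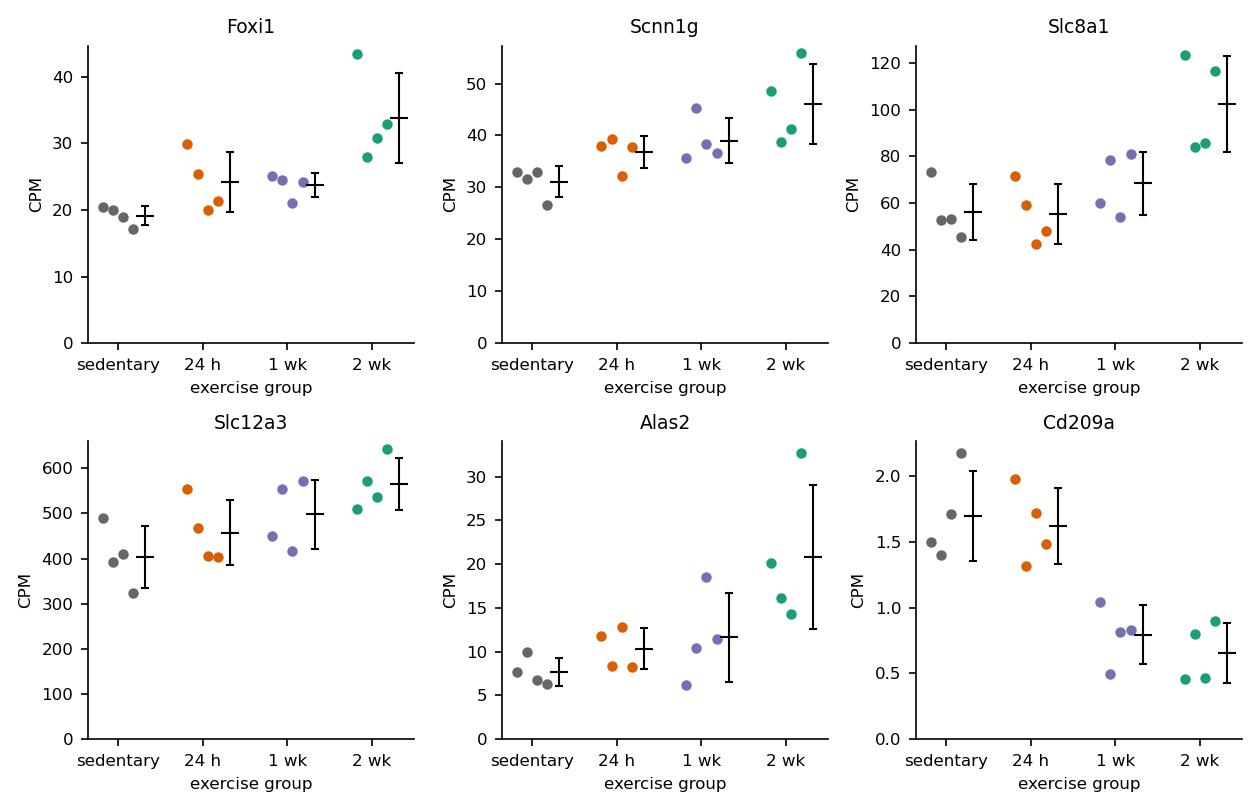
CPM of Foxi1, Scnn1g, Slc8a1, Slc12a3, Alas2 and Cd209a in each of 16 libraries by exercise group; points are libraries, and the bars beside them the mean and SD (n = 4). All 4 libraries at 2 wk lie above all sedentary libraries for the first 5 genes and below them for Cd209a, and none of the 6 passed edgeR's test against sedentary mice.

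Erythroid transcripts were higher at 2 wk, with 6 of 6 positive log2 fold changes, a median of 1.25 and 5 passing when adjusted over the list alone, but with an estimated correlation the list was not called (adjusted p = 0.158). The heme synthesis gene Alas2 was at 20.8 ± 8.28 CPM against 7.65 ± 1.64 CPM (1.44 ± 0.29, edgeR adjusted p = 0.21), and the globin gene Hba-a1, one of a pair of near-identical copies whose counts are therefore uncertain, at 192 ± 84.3 CPM against 78.5 ± 23.4 CPM. Cholesterol synthesis was higher (median 0.23, positive in 13 of 14, adjusted p = 0.158 with an estimated correlation), with 4 genes passing when adjusted over the list alone, among them Lss (0.39 ± 0.10). In the fatty acid oxidation list (median 0.11, adjusted p = 0.313 with an estimated correlation) the 3 genes that passed when adjusted over the list alone were the fatty acid hydroxylases Cyp4a14 (3.02 ± 0.81, 227 ± 150 CPM against 27.9 ± 8.07 CPM) and Cyp4a10 (0.56 ± 0.18), which are close paralogs, and Ucp2 (0.70 ± 0.21). Oxidative stress (0.09) and heat shock genes (0.28) were higher, and androgen-responsive kidney genes (−0.21) and replication-dependent histones (−0.14) lower. With an estimated correlation none of these 4 was called (adjusted p = 0.21, 0.621, 0.21 and 0.367 in that order). Of these 4 lists only 2 histone genes, Hist1h1c (−0.39 ± 0.10) and Hist1h4i (−0.46 ± 0.13), passed when adjusted over the list alone. Camera's adjusted p for these 7 lists was 9.89e-07, 1.29e-05, 0.00208, 0.0257, 0.0426, 0.00151 and 0.00519 in the order given. By fry, 4 lists passed at 2 wk, those of intercalated cells, erythroid cells, cholesterol synthesis and dendritic cells, each with an adjusted p of 0.04995. The intercalated and erythroid lists share Slc4a1, so they are not independent of each other. Heat shock was no longer called without the 1st (0.0641), 2nd (0.0598) or 3rd (0.0776) sedentary library or the 1st (0.351) or 3rd (0.329) 2 wk library. Oxidative stress was lost without the 1st (0.0588) or 2nd (0.0506) sedentary or the 1st 2 wk library (0.189), and histones without the 2nd sedentary (0.0549) or the 4th 2 wk library (0.0933). The fatty acid oxidation median was 0.071 without the 1st and 0.065 without the 4th 2 wk library, and the heat shock median 0.11 without the 1st. The histone median was −0.21 without the 1st sedentary library and −0.09 and −0.28 without the 2nd and 3rd 2 wk libraries.

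The lists of most immune cell types were lower at 2 wk by camera, but none was called with an estimated correlation (adjusted p of 0.158 to 0.469). Medians were −0.35 for MHC class II presentation (10 of 10 negative), −0.29 for macrophages (12 of 13), −0.48 for dendritic cells (7 of 9), −0.67 for monocytes (8 of 9), −0.37 for T cells (9 of 9), −0.76 for natural killer and cytotoxic cells (5 of 6), −0.49 for B cells (7 of 8), −0.62 for plasma cells (7 of 8) and −0.22 for the interferon response (14 of 20). Endothelial genes had a median of −0.26 (10 of 10 negative). Those that passed when adjusted over the list alone were Cd209a (−1.35 ± 0.26, 0.66 ± 0.23 CPM against 1.70 ± 0.34 CPM, adjusted p over all genes 0.141) and Itgax (−0.83 ± 0.23) among dendritic cell genes, the chemokine receptor Ccr2 of monocytes (−0.83 ± 0.24), and the cytotoxic granule genes Gzma (−1.29 ± 0.42) and Prf1 (−1.29 ± 0.45), both under 0.4 CPM. The other 7 of these 10 lists had no such gene. The adjusted p by camera was 5.65e-05 for MHC class II, 0.000733 for macrophages, 0.00181 for dendritic cells, 0.00479 for monocytes and for natural killer cells, 0.00239 for T cells, 0.0297 for B cells, 0.00654 for plasma cells, 0.0043 for the interferon response and 0.000631 for endothelium. The dendritic cell median was −0.021 (adjusted p = 0.041) when only genes of at least 1 CPM in 4 libraries were kept. With an estimated correlation the adjusted p in the order of the 10 lists was 0.26, 0.29, 0.158, 0.279, 0.162, 0.279, 0.469, 0.158, 0.469 and 0.369.

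The B cell call was lost without any one of the sedentary libraries (adjusted p = 0.0681, 0.0598, 0.297 and 0.0521 in their order) or of the first 3 at 2 wk (0.22, 0.107 and 0.122). Without the 3rd 2 wk library, monocytes (0.211) and natural killer cells (0.0812) were also lost, and without the 4th sedentary library monocytes (0.0516). The monocyte median was −0.43, −0.43 and −0.44 without the 1st, 3rd and 4th sedentary libraries and −0.38 and −0.42 without the 3rd and 4th 2 wk libraries. Over all libraries left out in turn it lay between −0.577 and −0.38, against −0.725 to −0.649 under the other settings. The low-count filter was redone in each fit that left out a library, so this shift cannot be laid to the library left out. The B cell median was −0.30 and −0.26 without the 2nd and 3rd sedentary libraries. The natural killer median was −0.51 without the 1st sedentary and −0.50 without the 1st 2 wk library, the endothelial median −0.15 without the latter, and the plasma cell median −0.97 without the 2nd sedentary library. Of the lists too short for the test, neutrophil genes summed to 2.42 ± 1.70 CPM at 2 wk and 1.72 ± 0.67 CPM in sedentary mice. Genes of the adrenal cortex and of skeletal muscle summed to 119 ± 14.4 and 26.5 ± 5.16 CPM at 2 wk and to 130 ± 12.5 and 27.2 ± 3.39 CPM in sedentary mice.

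The 1st 2 wk library stood apart in lists of other tissues, with a mean log2 CPM 1.75 above the sedentary mean for adipose genes and −1.24 for genes of the renal medulla. With that library and the 3rd 24 h library both left out, 5 lists were called at 24 h, 17 at 1 wk and 20 at 2 wk, and edgeR called 0, 0 and 1 genes. At 2 wk this ended 4 calls, those of the renal medulla (adjusted p = 0.0672), B cells (0.218), heat shock (0.218) and oxidative stress (0.203). With all libraries the list counts were 10, 15 and 22 of 45. Among lists not called, the median or mean and the test differed in sign for 9 at 24 h, 4 at 1 wk and 4 at 2 wk.

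EdgeR called 0 genes at 2 wk, where 1170 had an unadjusted p under 0.05 (648 higher and 522 lower). DESeq2 called 31 genes (19 higher, 12 lower) and voom with quality weights 7, all higher. Without the 3rd 2 wk library edgeR called 8 genes and without the 2nd 2. Next to Foxi1, the adjusted p was also 0.0591 for the fatty acid desaturase Scd2 (0.62 ± 0.10, 97.3 ± 10.2 CPM against 63.5 ± 3.62 CPM) and Ints6 (0.63 ± 0.11). The rest of the 10 with the smallest p were Acnat2 (0.88 ± 0.17) and Phactr1 (0.83 ± 0.16), each with an adjusted p of 0.141, and Hsd11b1, which regenerates corticosterone (−0.77 ± 0.16, 132 ± 30.2 CPM against 225 ± 36.7 CPM, adjusted p = 0.185), with Cd209a, Scnn1g, Alas2 and Slc8a1 described above. Ren1 (0.22 ± 0.30), Havcr1 (0.07 ± 0.66), Lcn2 (−0.16 ± 0.42), Adgre1 (−0.29 ± 0.26), Cd3e (−0.41 ± 0.33), Per1 (0.60 ± 0.27), Nr1d1 (0.11 ± 0.18), Arntl (0.28 ± 0.27) and Ddx3y (0.03 ± 0.19) had adjusted p of 0.657 to 0.987.

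The durations were also compared with each other. Between 2 wk and 24 h, edgeR called 2 genes, both lower at 2 wk. Asns was at 4.22 ± 0.63 CPM at 2 wk against 10.5 ± 0.93 CPM at 24 h (−1.31 ± 0.17, adjusted p = 0.00616), and Atf5 at 18.7 ± 1.82 CPM against 28.9 ± 1.40 CPM (−0.63 ± 0.09, adjusted p = 0.0121), with all 4 libraries of a group on one side for both. Their adjusted p without the 2nd 2 wk library was 0.0544 and 0.0671. For Atf5 it was also 0.0889 without the 1st and 0.0575 without the 4th 24 h library, and 0.0845 without the 4th 2 wk library, 0.107 with only the 8 libraries of the groups compared, and 0.361 against a 1.2-fold threshold. The count ranged from 0 without the 2nd to 6 without the 3rd 2 wk library, and was 3 without the 1st and 1 without the 4th. It was 7 without the 2nd 24 h library, and 1 without the 1st or the 4th. DESeq2 called 38 genes and voom with quality weights 4. Mitochondrially encoded genes were higher at 2 wk than at 24 h (median 0.70, 6 of 7 passing when adjusted over the list alone) and plasma cell genes lower (median −0.71, 3 of 8). These 2 lists passed fry, each with an adjusted p of 0.0171. In all, camera with the preset correlation called 25 lists, 8 higher and 17 lower at 2 wk, and none with an estimated correlation, where the smallest adjusted p was 0.106.

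Between 1 wk and 24 h, camera with the preset correlation called 17 lists, 2 higher and 15 lower at 1 wk, with a smallest adjusted p of 0.102 with an estimated correlation. Mitochondrially encoded genes were higher (median 0.61, 7 of 7 passing when adjusted over the list alone). Macrophage (−0.57, 7 of 13), fibroblast (−0.50, 7 of 12), heat shock (−0.44, 7 of 13) and endoplasmic reticulum stress genes (−0.40, 3 of 14) were lower. For these 5 lists camera's adjusted p was 1.6e-09, 4.73e-09, 7.77e-10, 1.08e-05 and 1.78e-07. With an estimated correlation the adjusted p was 0.102, 0.102, 0.102, 0.291 and 0.192. In the macrophage, fibroblast, heat shock and endoplasmic reticulum lists the 3rd 24 h library had the highest mean of all libraries. It lay 0.60, 0.62, 1.33 and 1.03 above the sedentary mean in that order. Lists were not refitted between durations with libraries left out or split in other ways. EdgeR called 0 genes, with 1153 at an unadjusted p under 0.05, while DESeq2 called 51 and voom with quality weights 0. Leaving out the 3rd 24 h library gave 662 genes at an unadjusted p under 0.05, where chance gives 806. Without the 2nd 24 h library edgeR called 2 genes, among them Col1a2. Between 2 wk and 1 wk, 8 lists were called, 5 higher and 3 lower at 2 wk, with a smallest adjusted p of 0.767 with an estimated correlation. Intercalated cells (0.28) and erythroid cells (0.60) were higher at 2 wk, each with a camera adjusted p of 0.00137. EdgeR called 0 genes, with 738 at an unadjusted p under 0.05, while DESeq2 called 3 and voom with quality weights 1.

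Log2 fold changes against sedentary mice were compared across durations over 16126 genes, which are not independent replicates. Pearson's r was 0.510 for 24 h and 1 wk, 0.484 for 24 h and 2 wk, and 0.592 for 1 wk and 2 wk. With all 16 libraries simulated, the shared sedentary ones included, and no group changed, r was 0.497, 0.498 and 0.500. The covariance was 0.0332, 0.0338 and 0.0378 against simulated values of 0.0245, 0.0243 and 0.0244. When each duration was set against a different pair of sedentary libraries, the mean r was 0.194, 0.192 and 0.255 over 6 splits. Since edgeR called 0 genes in each comparison, 0 were shared, while the DESeq2 calls shared 8. Those were Rpl28-ps1 and Gm11273 at 24 h and 1 wk, Lipo3, Hist1h1c, Il17re, Pprc1 and Acnat2 at 24 h and 2 wk, and Cd209a at 1 wk and 2 wk.

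**Figure D4:**
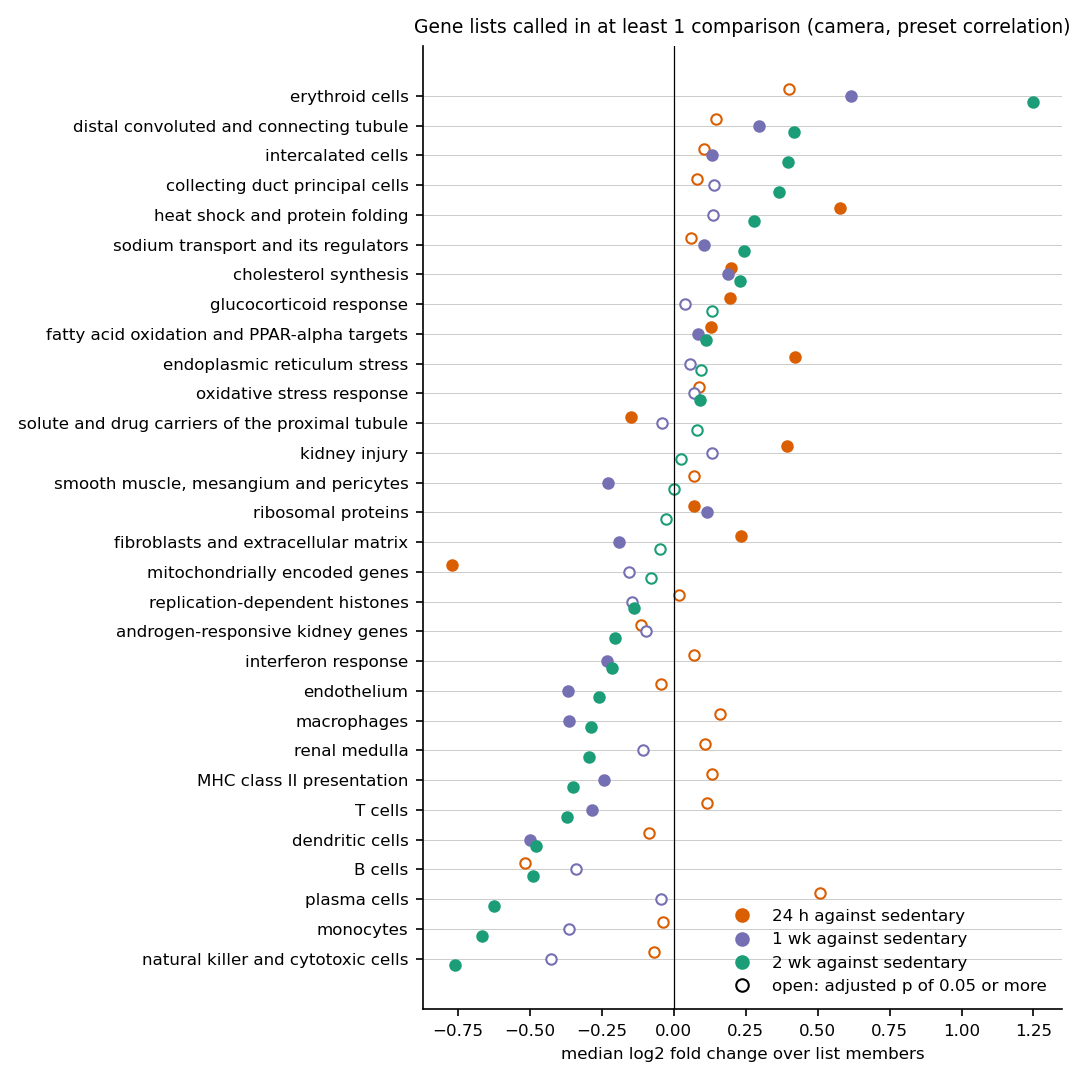
Median log2 fold change against sedentary mice, over the members of each gene list, for the lists called by camera with a preset correlation in at least 1 of 3 comparisons; filled points have an adjusted p under 0.05, and none of them does with an estimated correlation. Medians reach −0.77 for mitochondrially encoded genes at 24 h and 1.25 for erythroid cells at 2 wk.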

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

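The second lists of ATF4 targets and of intercalated markers and the other splits of the libraries were set before their results were seen; the remaining tests of explanations in this part were chosen only after the result was seen.

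Mitochondrially encoded transcripts were lower at 24 h (median log2 fold change −0.77, lower in all 4 libraries than in any sedentary library), though not called with an estimated correlation (adjusted p = 0.198). The exact test of their share of counts gave 0.0286, the smallest p that 4 libraries against 4 allow, and an adjusted p of 0.0857. Fewer mitochondria-rich cells are argued against by the nuclear respiratory chain genes, whose median was −0.008, and the scaling by a median of −0.764 with RLE size factors and by raw shares of counts that do not overlap. A difference in poly(A) capture or preparation cannot be told apart from the group, because library numbers ran in group order; histone transcripts, most of which lack a poly(A) tail, had a median of 0.018. An ATF4-type stress response, of which Asns is a known target, may accompany the change. A second list of 21 ATF4 targets without the genes seen so far had a median of 0.153 with 17 positive and fry's p = 0.0108, but its mean was 0.25 in the 3rd 24 h library against 0.05 to 0.10 in the others and the exact permutation test gave p = 0.0857, so this stays open.

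Distal nephron genes were higher at 2 wk (medians of 0.37 to 0.42 in 3 segment lists), though not with an estimated correlation (adjusted p = 0.158, 0.158 and 0.279). A lower share of proximal tubule cells would by itself raise every other cell type alike, whereas the endothelial median was −0.261. That fall may have a separate cause, so it cannot exclude a lower share. Relative to the sedentary mean, list means of the convoluted proximal tubule were 0.13, 0.33, −0.15 and −0.06 in the 2 wk libraries. Those of the straight part were −0.22, −0.25, 0.05 and −0.05, so both lists went both ways and this stays open. Pieces taken at another depth of the cortex cannot be told apart, since the renal medulla list (median −0.294) was lower by camera but not with an estimated correlation (adjusted p = 0.363), with list means of −1.24, −0.72, 0.20 and −0.22 in the 2 wk libraries. A larger share of intercalated cells may contribute. A second list of 13 intercalated markers had a median of 0.217 with 12 positive, camera's p = 0.0334 with an estimated correlation and fry's p = 0.0174, but the exact permutation test gave p = 0.0571, so this too stays open, as does higher expression per cell, which was not tested.

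Endothelial genes and those of several immune cell types were lower at 1 wk and 2 wk by camera, but no such list was called with an estimated correlation (adjusted p of 0.435 or more at 1 wk and 0.158 to 0.469 at 2 wk). Less blood left in the kidneys is argued against at 2 wk by the erythroid median of 1.248, unless reticulocytes made up more of the blood, which was not measured. At 1 wk the erythroid median was 0.615, but the list mean was 1.18 in 1 library and −0.23 to 0.43 in the others, and this explanation cannot be told apart. Dilution by a larger share of tubule cells may also lower these lists. It cannot be told apart at either time, because the podocyte medians, 0.025 at 2 wk and −0.043 at 1 wk, rest on members that went both ways.

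Other splits of the 8 libraries of a comparison into 4 and 4, 35 with the real one, were refitted in the same way. Taken alone, this test excluded chance for the number of genes at an unadjusted p under 0.05 at 24 h, which was 1439 and at most 1128 in the other splits, so that 1 of 35 reached it. That is the smallest share these splits allow, and it would not hold after adjustment over the 6 comparisons. Without the 3rd 24 h library the number at 24 h was 883, where chance gives 806. In the other fits that left out a library it was 1048 to 1672. The splits were not repeated with a library left out. Chance was not excluded for that number in any other comparison. At 1 wk 8 splits reached the 975 genes found (highest other 2191), at 2 wk 6 reached 1170 (2450), between 1 wk and 24 h 13 reached 1153 (3156), between 2 wk and 1 wk 18 reached 738 (4512), and between 2 wk and 24 h 7 reached 1549 (2547). It was not excluded for the called lists either. Of the 35 splits, 21 called at least the 10 lists of 24 h (highest other 20), 5 the 15 lists of 1 wk (21) and 2 the 22 lists of 2 wk (22). For called genes, the 2 between 2 wk and 24 h were reached by 3 splits (highest other 2) and the 2 across all groups by 6 of 100 regroupings (highest other 251), so chance was not excluded. Where edgeR called 0 genes all 35 splits reach that number, with a highest other of 0 at 24 h, 2 at 1 wk, 1 at 2 wk, 37 between 1 wk and 24 h and 1861 between 2 wk and 1 wk.

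In the comparison of 2 wk with 1 wk, 4 splits called between 393 and 1861 genes, which points to a structure of the samples other than duration. The split with 1861 genes joined the 1st, 2nd and 4th 2 wk libraries and the 4th 1 wk library. All 4 splits set the 2nd 2 wk and the 4th 1 wk library against the 2nd and 3rd 1 wk libraries, and place the other 4 in different ways. On the first principal component over all 16 libraries these lie at −32.2 and −26.0 against 8.27 and 30.4. What the structure is was not tested beyond the correlations of this component with list means given at the end.

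Single libraries stood apart from the others of their group in 10 of 172 groups of values tested by Dixon's ratio of gap to range, where about 1 in 20, or 8.6, arise by chance. Total counts were 56960000 in the 1st sedentary library against 45850000 to 47280000 in the others (ratio 0.872), and 66850000 in the 2nd 2 wk library against 43600000 to 46230000 (0.887). Slc9a3 was at 93.1 CPM in the 1st sedentary library against 83.0 to 84.2 (0.887) and at 134.9 CPM in the 4th 1 wk library against 73.8 to 82.7 (0.854). Havcr1 was at 25.85 CPM in the 4th 24 h library against 3.42 to 6.97 (0.842) and at 10.7 CPM in the 3rd 1 wk library against 2.15 to 3.30 (0.866). Per1 was at 37.8 CPM in the 4th 2 wk library against 14.5 to 16.6 (0.909). Ints6 was at 9.78 CPM in the 3rd sedentary library against 8.13 to 8.19 (0.96), Phactr1 at 11.8 CPM in the 1st 24 h library against 7.94 to 8.45 (0.866), and Hsd11b1 at 223 CPM in the 4th 24 h library against 169 to 171 (0.973).

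The effects at 2 wk and 24 h differed by direct tests for 2 genes (edgeR) and 2 lists (fry), but neither list was called with an estimated correlation (smallest adjusted p = 0.106). The exact test of list means (adjusted p = 0.184) cannot decide this. Its p cannot fall below 0.0286 with 4 libraries against 4, before adjustment over 45 lists. Without the 2nd 2 wk library the adjusted p of both genes was over the threshold (0.0544 and 0.0671), and 3 of 35 splits called as many genes. The log2 fold change of 2 wk over 24 h was −1.314 for Asns and −0.628 for Atf5, and its median was −0.706 for plasma cell genes and 0.705 for mitochondrially encoded genes.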

How the results depend on the processing

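The exact test of list means, the fits without 2 libraries that stood apart or without mitochondrially encoded genes and the most abundant unnamed ID, and DESeq2's likelihood ratio test were chosen only after the data were seen; the other alternatives were planned. Of the values for single genes under an alternative, 955 kept their direction and side of the threshold, 83 passed it in addition, 7 lost it and 53 changed sign; of those for single lists, 571 kept both, 221 lost the call and 1 changed sign. With RLE scaling the counts of called genes did not change. For every change given here the cause was not tested, except that leaving out libraries or groups leaves fewer samples. In simulated counts with the sizes of these libraries, edgeR recovered 41.8% to 62.7% of 1.5-fold and 70.1% to 77.6% of 2-fold changes. At 24 h, 1 wk and 2 wk, DESeq2 made 14, 22 and 24 false calls there, edgeR 6, 6 and 10, and voom 5, 6 and 10.

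The counts of called genes against sedentary mice, 0 at each duration in edgeR, were 78, 12 and 31 with DESeq2 and 59, 6 and 7 with voom and quality weights at 24 h, 1 wk and 2 wk. Without a low-count filter they were 9 at 24 h and 5 at 2 wk, with only the 8 libraries compared 28 and 2, and without the 2 libraries that stood apart 1 at 2 wk. Between 1 wk and 24 h DESeq2 called 51, and between 2 wk and 1 wk 3, with 1 by voom. The 2 genes between 2 wk and 24 h became 38 with DESeq2, 4 with voom, upper-quartile scaling, the 1 CPM filter or without mitochondrially encoded genes, 8 with no filter, and 1 at an adjusted p of 0.01 or against 1.2-fold. Asns kept a log2 fold change of −1.402 to −1.25 there with each library left out (adjusted p = 0.00789 to 0.0544), and Atf5 one of −0.689 to −0.579 (0.00789 to 0.0889). Across all groups the 2 genes became 158 with DESeq2's likelihood ratio test, 10 with no filter and 0 at an adjusted p of 0.01. DESeq2 called 169 genes in at least 1 comparison of 2 groups, which is not a test of all groups together. Shared calls went from 0 to 8 with DESeq2. The correlations between durations were 0.194, 0.192 and 0.255 with the sedentary libraries split. Leaving out each library in turn gave 0 to 1 genes at 1 wk, 0 to 8 at 2 wk, 0 to 2 between 1 wk and 24 h, 0 to 7 between 2 wk and 24 h and 0 to 5 across all groups.

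The called lists, 10 at 24 h, 15 at 1 wk and 22 at 2 wk, were 0, 0 and 0 with an estimated correlation, 1, 0 and 4 with fry, 0, 0 and 0 with the exact test of list means, and 5 at 24 h without the 2 libraries that stood apart. The exact test could hardly pass after adjustment over 45 lists, since its smallest possible p is 0.0286. Its zero counts therefore say little about these lists, and they are part of the 221 lost calls given above. Leaving out each library gave 5 to 12 at 24 h, 9 to 20 at 1 wk and 18 to 22 at 2 wk. Calls lost under other planned settings were the glucocorticoid list at 24 h (adjusted p = 0.0584 with RLE scaling, 0.0828 with voom), T cells (0.123 with voom) and dendritic cells (0.174 with the 1 CPM filter, where the median was −0.054) at 1 wk, and B cells (0.13 with voom), heat shock (0.196 with voom) and oxidative stress (0.0562 with the 1 CPM filter) at 2 wk. The dendritic cell median at 2 wk was −0.021 with the 1 CPM filter. Under that filter 17 of the 22 called lists at 2 wk kept the call and 1 lost it. At 1 wk 13 of the 15 kept it and 1 lost it. The remaining called lists had fewer than 5 members left there and could not be tested, so they were neither kept nor lost. The sodium transport median at 1 wk was −0.005 with voom.

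Single genes changed sign under some settings, none of them called in edgeR. At 24 h Cd3e was at 0.002 with DESeq2 and 0.003 with RLE scaling or only 8 libraries, and Ddx3y at 0.049 with voom. Slc9a3 was at −0.047 with voom at 1 wk, and at 2 wk at −0.031 with upper-quartile scaling, −0.009 with the 1 CPM filter, −0.002 with 8 libraries and −0.055 with voom, where Ddx3y was at 0.0 with upper-quartile scaling. Leaving out each library gave, at 24 h, −0.294 to 0.212 for Cd3e, −0.031 to 0.288 for Nr1d1, −0.092 to 0.153 for Ddx3y and −0.006 to 0.458 for Arntl. At 1 wk it gave −0.146 to 0.173 for Nr1d1, −0.245 to 0.033 for Arntl, −0.251 to 0.093 for Per1, −0.137 to 0.195 for Ren1, −0.257 to 0.075 for Ddx3y, −0.258 to 0.839 for Havcr1, −0.138 to 0.658 for Lcn2 and −0.115 to 0.212 for Slc9a3. At 2 wk it gave −0.203 to 0.422 for Havcr1, −0.12 to 0.199 for Ddx3y, −0.065 to 0.05 for Slc9a3, −0.022 to 0.303 for Nr1d1, −0.03 to 0.394 for Ren1 and −0.358 to 0.066 for Lcn2.

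The replicate numbers of the titles were not taken to pair libraries across groups, since the labels do not say that equal numbers share anything. The mean correlation of deviations from the group means was 0.057 for libraries of the same number and −0.019 for others, 8 of 24 same-number pairs were over 0.1, of which 5 were pairs of number 3 (0.151 to 0.375), and 5 of 16 libraries matched their own number best. With the number as a block, edgeR called 5 genes at 2 wk, 11 between 2 wk and 24 h and 5 across all groups, Ddx3y at 24 h was at 0.0 and Ren1 at 1 wk at −0.021, and the glucocorticoid list at 24 h (adjusted p = 0.0647), T cells at 1 wk (0.0548) and heat shock at 2 wk (0.0527) were no longer called.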

Other observations

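The genes given here and the correlations of list means with the first principal component were chosen only after the data were seen.

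Several genes of single pathways stood out in lists that were not called. In glucose metabolism at 24 h, glucose-6-phosphatase, G6pc, which releases glucose in gluconeogenesis, was at 380 ± 88.5 CPM against 609 ± 78.4 CPM in sedentary mice (SD, n = 4; −0.68 ± 0.17), and the glycolytic Pfkp at 50.5 ± 5.42 CPM against 36.3 ± 3.76 CPM (0.48 ± 0.10). Both passed when adjusted over the list alone, with edgeR's adjusted p over all genes of 0.202 and 0.162. At 2 wk G6pc was again lower (−0.62 ± 0.17), while Pck1, which catalyses an earlier step of gluconeogenesis, was higher (0.56 ± 0.18, 1986 ± 644 CPM against 1346 ± 136 CPM), each passing over the list alone. Among oxidative stress genes at 24 h, Gclc, which limits glutathione synthesis, was at 464 ± 36.0 CPM against 250 ± 50.2 CPM (0.89 ± 0.21, adjusted p = 0.179).

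In the list of renin-angiotensin, nitric oxide and natriuretic signalling, which moved in no one direction (medians of −0.05 at 24 h and 0.01 at 2 wk), single genes differed both ways. By fry's test for change in either direction its adjusted p was 0.00384 at 24 h and 0.0268 at 2 wk. It was not alone, since 4 lists passed that test at 24 h and 5 at 2 wk. The inducible nitric oxide synthase Nos2 was lower at both times (−0.865 ± 0.209 and −0.746 ± 0.205), at 0.48 ± 0.06 and 0.52 ± 0.07 CPM against 0.87 ± 0.11 CPM, and passed over the list alone at both. Cyp4a14 and Cyp4a10, which are also in the fatty acid oxidation list described above, passed over the list alone at 2 wk. Clu, of the kidney injury list, was higher at 2 wk than in sedentary mice (0.92 ± 0.20, 503 ± 169 CPM against 266 ± 57.4 CPM) although that list was not called there (adjusted p = 0.88). It was the 1 gene of the list that passed over the list alone.

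The first principal component, with 17.6% of the variance, was compared with the means of 45 lists over 16 libraries by permutation tests. The proximal convoluted tubule list had r = −0.818 (p = 7e-05, adjusted p = 0.00225) and rho = −0.821 (p = 0.00017, adjusted p = 0.00765). After the group means were removed r was −0.776, and without the 2 libraries farthest from the median of the component it was −0.809. Solute and drug carriers of the proximal tubule had r = −0.826 (adjusted p = 0.00225) and rho = −0.797 (adjusted p = 0.00833), but −0.662 without the 2 libraries. By r, though not by rho, ribosomal proteins went the other way most strongly, with r = 0.809 (adjusted p = 0.0042). Their rho of 0.644 had an adjusted p of 0.0548. The renal medulla list was also positive, with r = 0.628 (adjusted p = 0.0342) and rho = 0.724 (adjusted p = 0.0217), 0.529 within groups and 0.56 without the 2 libraries. The sodium transport list was negative, with r = −0.678 (adjusted p = 0.0342) and rho = −0.726 (adjusted p = 0.0217). Its r was −0.655 within groups and −0.674 without the 2 libraries. In all, 13 lists passed at an adjusted p under 0.05 by r and 5 by rho. The component is computed from all genes, those of the lists included, so it is not independent of them.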
